A study of Lactiplantibacillus plantarum with 16 samples.

How the data were processed

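RNA of Lactiplantibacillus plantarum was compared on 16 two-colour arrays. The strains were the wild type WCFS1 and a mutant whose gshF gene carries an insertion named cam in its label, and each was sampled before (0 min) and 10 and 30 min after addition of 10 mM hydrogen peroxide. The labels name 12 RNA extracts, 2 per strain and time, and each extract was hybridised on 2 or 3 arrays, so that the arrays form loops. Nothing says that the 2 extracts of a condition came from separate cultures, and the spread between them may be technical. The arrays carry 2 label prefixes, taken as 2 slides of 8 arrays each.

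The scanner files hold spot and local background intensities in both dyes, as deposited, quantified with ImaGene per the file headers, with no normalization. The version of that program is not given in the sources used here. The software's flags and its empty-spot marks came with them, and from the values an empty spot lies at most 2 background SDs above its background. The authors' deposited value table holds log2 ratios per spot. For 15 arrays their ranks follow Cy3 over Cy5 of the scanner intensities (rank correlation with Cy5 over Cy3 -1.00), the opposite of the direction in the series text, and the columns are not centred. In the Cy3 over Cy5 direction the column medians were -2.90, 2.72, 1.02, -0.90, -1.40, 1.67, 0.98 and 3.43 for the arrays of the first slide and 4.63, -0.84, 1.78, 4.14, 3.25, 0.93, 5.40 and 3.87 for those of the second. The direction of every ratio was taken from the dye labels of each array, since the series text's statement that Cy3 held the wild type conflicts with most of them.

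The scanner file of 1 array (mutant replicate 2, 30 min in Cy3 and 0 min in Cy5) is of another array layout and did not match its own deposited ratios (rank correlation -0.03). A first fit took this array from its deposited ratios, as 1 of 16. After the counts of that fit had been seen, the SD of this array's gene ratios was found to be 1.54. The others had 0.271 to 0.738, but from background-corrected scanner intensities. Among the deposited ratios its SD was 1.92, within the 0.72 to 2.15 of the other arrays. The gap therefore does not show that the array itself differs in scale. The array was left out, because the fixed processing starts from scanner intensities. The reported results therefore rest on 15 arrays and not on the 16 of the fixed design. This choice lowers the counts in the mutant strongly, and the counts with 16 arrays stand beside them. Without this array, replicate 2 of the mutant at 0 min rests on 1 array.

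Background was corrected by normexp with an offset of 50, arrays were normalized by within-array loess, and flagged and control spots received weight 0. Spots of a probe were averaged, then the probes of a gene. A gene needed a value on at least 10 arrays, a minimum set after the files had been opened but before any result. Of 3092 gene IDs on the array, 2453 were tested. The model was fitted with limma 3.58.1 in R 4.3.3, with the 6 conditions and a dye term as fixed effects and the extract as a random effect. The ratio of extract to array variance, estimated by restricted likelihood over all genes, came out at 0, so the fit treats arrays as independent and its p-values measure the spread between arrays, repeat hybridisations of an extract included. The fit on 12 estimated extract levels called between 0 and 2 genes per comparison. It treats the levels as independent, so their spread holds differences between extracts and the error of the arrays that link them. The variance ratio was 12 on slide 004 alone and between 0 and 0.2 in the other fits. On slide 003 alone the ratio was set to 0, since 1 residual degree of freedom was left. A complete gene has 9 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p below 0.01 and a fold change of at least 1.5, thresholds that the series text names. The number of arrays limits the precision.

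On simulated data with 2453 genes and no variance between extracts, the test of the wild type at 30 min recovered 8 of 50 genes changed 1.5-fold, 39 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 1 false call. For the mutant at 30 min it recovered 7, 24 and 49 of 50, with 1 false call. With an extract variance 0.5 times the array variance it recovered 1, 22 and 47 of 50 in the wild type, with 0 false calls, and 0, 9 and 41 of 50 in the mutant, with 3 false calls.

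The files do not pair gene IDs with names. The reference table, of another strain's assembly, matched 0 of 3092 IDs. The 21 fixed gene lists, which rest on names, were therefore not applied, and gshF could not be looked up. Genes were to be named by a fixed rule, up to 10 with the largest rise and 10 with the largest fall among those called and moving the same way in both replicate numbers; as no names exist, at most 2 IDs per direction are given for each comparison, by their locus tag. A gene of a count of 5 or fewer that falls outside the rule, and the tags next to lp_2335, were chosen after their values were seen.

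The design, the gene lists, the rule for named genes and a first set of alternatives were fixed before the data were examined. That set held other background, normalization, filter and probe summaries, the deposited table, fits without the extract effect or dye term, a fit on 12 extract levels, a replicate block, a dye term per slide, each slide alone, a looser threshold and leaving out each extract. The 16 arrays and the fit on them without the extract effect belonged to the fixed design. Chosen after seeing the data were leaving out 1 array and, for the fits that keep it, entering it from its deposited ratios. The alternatives chosen after seeing the data were slide 004 alone without the extract effect, fits without the weak array that pairs 0 and 30 min and without the other 3 weak arrays, ignored spot flags, the deposited table with median centring, genes measured on all 15 arrays, and a fit without the 4 arrays on which under 20% of gene spots lay above background in a channel. Figures were drawn with matplotlib.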

Results

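The series asks how a wild-type strain of Lactiplantibacillus plantarum, a lactic acid bacterium, and its gshF mutant change their transcripts after hydrogen peroxide. GshF is known as a bifunctional glutathione synthetase, an enzyme that makes the antioxidant glutathione. Each of the 6 conditions had 2 RNA extracts. The limma p-values of the 15-array fit measure the spread between arrays, repeat hybridisations of an extract included, and not that between extracts. Signal was weak. Between 30.0% and 61.7% of gene spots per array lay above local background in Cy3, and between 4.5% and 67.4% in Cy5. On 4 arrays under 20% did so in Cy5 (4.5%, 8.4%, 9.6% and 15.6%), and 3 of these 4 carried wild-type 30 min RNA in that channel. All 4 lie on slide 004, whose other arrays had 23.8% to 67.4% above background in Cy5, so weak signal and slide overlap but do not coincide. Only 3 of the 15 arrays pair 0 min with a later time, 1 per strain for replicate 1 on slide 003 and 1 of the weak arrays for wild-type replicate 2 on slide 004. All changes from 0 min rest on these 3, so for them weak signal and slide cannot be told apart. Among the 15 arrays, the mutant's 0 min replicate 2 was hybridised only against wild-type 0 min replicate 2. The mutant's replicate 2 changes from 0 min therefore run through that weak array too. The disrupted gene could not be checked, since the files do not pair gshF with an ID.

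**Figure D1:**
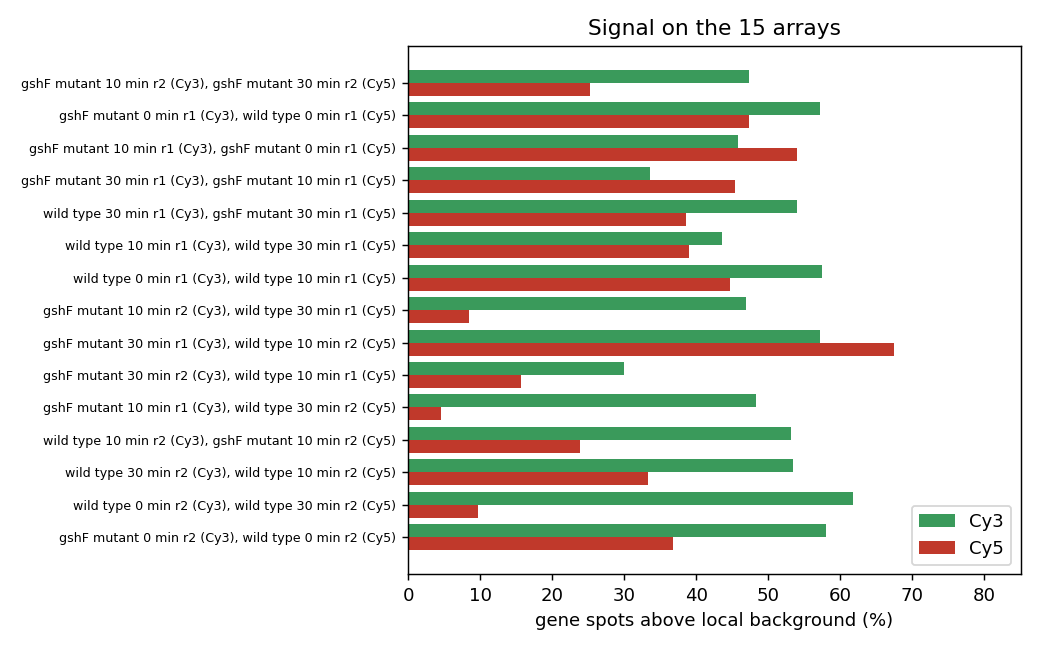
Percent of gene spots above local background on each of the 15 arrays used, with Cy3 in green and Cy5 in red and the 2 extracts of each array named at the left (r, replicate). Cy5 falls to 4.5%, 8.4% and 9.6% on 3 arrays with wild-type 30 min RNA in that channel.

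In the wild type, lp_3058 and lp_2113 rose most among the called genes after 10 min of peroxide. lp_3058 rose by 5.18 on the log2 scale (SE 0.82, n = 2 extracts per time, limma adjusted p = 0.010), by 7.21 in replicate 1 and 2.82 in replicate 2; it was above background on 3 of the 4 arrays with 0 min RNA. lp_2113 rose by 2.91 (SE 0.41, limma adjusted p = 0.0067), 7.50-fold, by 3.33 and 1.76 in the 2 replicates. The largest falls among called genes were those of lp_1572 (log2 change -1.78, SE 0.27, limma adjusted p = 0.0081) and lp_0609 (-1.73, SE 0.26, limma adjusted p = 0.0081). They were at -2.31 and -2.25 in replicate 1 but -0.58 and -0.61 in replicate 2. In all, 3 genes rose and 4 fell. At an adjusted p below 0.05 with no fold minimum 218 genes rose and 279 fell. Without the 4 weakest arrays, an alternative chosen after seeing the data, 247 rose and 295 fell, and these 542 included all 7. That fit, like slide 003 alone, keeps 1 array per strain from 0 min, both of replicate 1, so no second extract repeats the step. Leaving out only the weak array that pairs 0 and 30 min gave 568 calls, and leaving out the other 3 weak arrays gave 2, with 0 of the 7. A fit on 12 extract levels called 0, with 133 at an unadjusted p under 0.05, and leaving out 1 extract gave 0 to 497. Slide 003 alone gave 550 calls and slide 004 alone gave 0 by limma (138 at an unadjusted p under 0.05), and across 1799 genes their changes correlated with r = 0.14. The slide 004 fit used an extract variance ratio of 12; with none it also called 0, with 81 at an unadjusted p under 0.05. On slide 004 the change of lp_3058 was 1.64, that of lp_2113 2.58, that of lp_1572 -0.42 and that of lp_0609 -0.44.

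After 30 min, lp_2113 had the wild type's largest rise among called genes that moved the same way in both replicates. It reached a log2 change of 4.66 (SE 0.41, n = 2 extracts per time, limma adjusted p = 7.8e-05), 25.2-fold over 0 min. It rose by 4.03 in replicate 1 and by 4.53 in replicate 2. lp_1836 rose by 3.30 (SE 0.42, limma adjusted p = 0.0013), a 9.87-fold change, by 4.54 and 2.02 in the 2 replicates. lp_1025 changed by -2.03 (SE 0.19, limma adjusted p = 7.8e-05), with -2.00 and -2.01 in the 2 replicates, and lp_1572 by -1.70 (SE 0.27, limma adjusted p = 0.0087), with -2.46 and -0.69 in the 2 replicates, being above background on 3 of the 6 arrays with 30 min RNA. Of 2453 genes, 6 rose and 4 fell. Leaving out only the weak array that pairs 0 and 30 min gave 521 calls and leaving out all 4 weak arrays 503, on replicate 1 alone for the step from 0 min. Leaving out the other 3 gave 2. The fit on 12 extract levels called 2, and leaving out 1 extract gave 2 to 471. Slide 003 alone gave 424 calls and slide 004 alone 0 by limma (124 at an unadjusted p under 0.05), with r = 0.57 between the slides; on slide 004 lp_2113 changed by 4.84, lp_1836 by 2.27, lp_1025 by -2.16 and lp_1572 by -0.79.

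Between 10 and 30 min in the wild type, lp_1556 rose by 1.40 (SE 0.21, limma adjusted p = 0.0081) and lp_1269 by 1.03 (SE 0.16, limma adjusted p = 0.0081); under median centring the latter turned to -0.34. lp_1025 fell further, with a log2 change of -1.14 (SE 0.14, limma adjusted p = 0.0040), and lp_0957 changed by -1.04 (SE 0.16, limma adjusted p = 0.0081). In all 5 genes rose and 3 fell. With 16 arrays limma called 0 at the estimated extract variance ratio of 0.05, with 304 at an unadjusted p under 0.05, and 13, including all 8, without the extract effect. The fit without the 4 weakest arrays called 70, including 7 of the 8; the changes on the 2 slides correlated with r = 0.61. limma called 0 on 12 extract levels (57 at an unadjusted p under 0.05), on slide 003 alone (559), on slide 004 alone (407) and under median centring (796), and 2 with the replicate block. Leaving out 1 extract gave 0 to 31, with 0 without wild type 10 min replicate 2, wild type 30 min replicate 1 or any of the 6 mutant extracts.

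In the gshF mutant after 10 min, limma called 0 genes, while 983 had an unadjusted p under 0.05 and 581 an adjusted p under 0.05, 274 of them higher and 307 lower. The log2 change of lp_2113 was 2.74 there and that of lp_1572 was -1.85, both with a limma adjusted p of 0.0103, above the threshold. With 16 arrays 185 genes rose and 226 fell. Without the weak array that pairs 0 and 30 min there were 560 calls, without all 4 weak arrays 563, and without the other 3 there were 37. Leaving out 1 extract gave 0 to 505, with 505 without wild type 0 min replicate 2 and 486 without wild type 30 min replicate 2, both on that weak array. The fit on 12 extract levels called 0 (176 at an unadjusted p under 0.05), slide 003 alone 496 and slide 004 alone 1, with r = 0.14 between the slides.

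In the mutant after 30 min, the genes below had the largest changes among called genes that moved the same way in both replicates. lp_1879 rose by 3.72 on the log2 scale (SE 0.80, n = 2 extracts per time, limma adjusted p = 0.0083), followed by lp_2113 with 3.03 (SE 0.51, limma adjusted p = 0.0060). The largest falls were in lp_1176, with -2.49 (SE 0.46, limma adjusted p = 0.0060), and lp_0267, with -2.46 (SE 0.40, limma adjusted p = 0.0060). At 30 min lp_1176 was above background on 1 of 5 arrays and lp_0267 on 2 of 5. The change of lp_0267 was -2.99 in replicate 1 and -0.48 in replicate 2, that of lp_1176 -2.94 and -1.27, and on slide 004 alone it was -0.14 and that of lp_1176 was -0.49, while lp_1879 changed by 3.08 there and lp_2113 by 2.95. A total of 103 genes rose and 120 fell. With 16 arrays 536 rose and 514 fell, and these included all 223. Without the weak array that pairs 0 and 30 min there were 695 calls and without all 4 weak arrays 682, while without the other 3 there were 110, of which 84 were among the 223. Leaving out 1 extract at a time moved the count of 223 to between 0 and 632; 12 extract levels gave 1 call, slide 003 alone 627 and slide 004 alone 1, with r = 0.27 between the slides. Between 10 and 30 min the mutant had 1 called gene, lp_1077, with a log2 change of -1.70 (SE 0.19, limma adjusted p = 0.0062), and 239 genes with an unadjusted p under 0.05; between the slides r was 0.02. limma called 0 there on 12 extract levels (23 at an unadjusted p under 0.05), with the replicate block (224), a dye term per slide (214), no background subtracted (165), background subtracted (293) or median centring (337). It also called 0 on each slide alone (639 and 482), without the weak arrays (444) and in 10 of the 12 fits that leave out 1 extract.

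**Figure D2:**
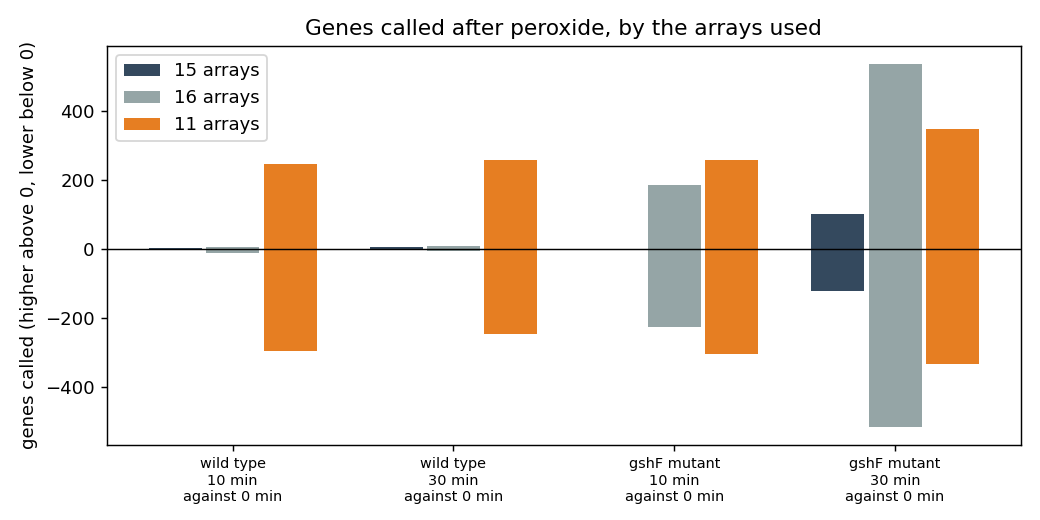
Number of genes called against 0 min in each strain at 10 and 30 min, with genes that rose drawn above 0 and genes that fell below 0. The 15-array fit is set beside fits with 16 arrays and with the 11 arrays left when the 4 weakest are removed. The 11-array fit called 542, 503, 563 and 682 genes and keeps 1 array per strain that pairs 0 min with a later time.

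The responses of the 2 strains ran in the same direction. Across 2453 genes, which are not independent replicates, the log2 changes of the strains correlated with r = 0.88 at 10 min and r = 0.81 at 30 min. Simulated unchanged genes on the same arrays gave 0.42 at both times, and the covariance was 0.274 at 10 min and 0.336 at 30 min, against 0.0215 and 0.0243 without effects. At an adjusted p below 0.05, 134 genes rose and 214 fell in both strains at 10 min, where independent lists would share 24.4 and 34.9. At 30 min 89 rose and 82 fell in both, where independent lists would share 21.4 and 14.1. At each time 0 genes moved in opposite directions. Both strains' changes rest on the same 3 arrays from 0 min. The simulated genes carry the noise of these arrays but no variance between extracts. Part of the excess may therefore come from deviations of extracts that both strains share through these arrays. The expected overlaps of independent lists allow for neither.

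**Figure D3:**
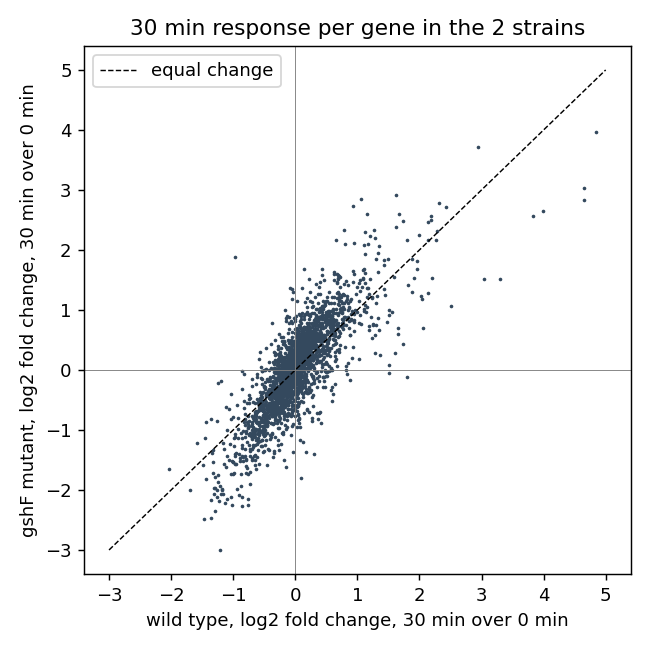
Log2 fold change at 30 min over 0 min for each of 2453 genes (points), wild type on the horizontal axis and gshF mutant on the vertical axis, with a dashed line of equal change. The points follow the line with r = 0.81 across genes.

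The difference in response between the strains was tested gene by gene. limma called 0 genes for the 10 min response, with 120 at an unadjusted p under 0.05. It called 0 for the 30 min response, with 464 at an unadjusted p under 0.05 and 4 at an adjusted p under 0.05. Those 4 differences, from -1.32 to -1.89, had adjusted p of 0.026 to 0.034 and were not called. The median unadjusted 95% interval of a gene extended 0.43 to either side at 10 min and 0.47 at 30 min on the log2 scale. Between the slides the differences correlated with r = -0.05 at 10 min and 0.47 at 30 min. With 16 arrays 2 and 8 genes were called, and without the 4 weakest arrays 0 and 5.

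Between the strains, lp_2335 and lp_2334, which have consecutive tags, were higher in the mutant. Averaged over the 3 times, lp_2335 was higher by 3.53 on the log2 scale (SE 0.30, limma adjusted p = 0.00015), or 11.6-fold, and lp_2334 by 3.30 (SE 0.34, limma adjusted p = 0.00033), or 9.86-fold. lp_2771 was lower, at -1.17 (SE 0.18, limma adjusted p = 0.0095), with -1.89 and -0.50 in the 2 replicates, -2.05 on slide 003 and -0.78 on slide 004. lp_0928 was lower, at -0.64 (SE 0.08, limma adjusted p = 0.00093), but turned to 0.25 under median centring. These 4 genes are all that were called for the mean; without the 4 weakest arrays there were 53. The fit on 12 extract levels called 0, with 90 at an unadjusted p under 0.05, and leaving out 1 extract gave 0 to 5. Between the slides r was 0.76. On slide 003 alone the difference of lp_2334 was 4.46 and lp_2335 was not tested; on slide 004 alone the differences were 3.34 and 3.88.

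At 0 min 0 genes were called between the strains, with 153 at an unadjusted p under 0.05. There lp_2335 was 3.57 higher in the mutant (SE 0.57, limma adjusted p = 0.025), by 1.87 and 4.47 in the 2 replicates. lp_2334 was 3.28 higher (SE 0.56, limma adjusted p = 0.029). lp_2335 had no value on the array that pairs the replicate 1 extracts at 0 min, so its 1.87 runs through arrays with later times. It was above background on 2 of the 4 wild-type arrays and 2 of the 3 mutant arrays. Without the 4 weakest arrays 2 genes were called, and between the slides r was 0.46. lp_2335 was the 1 gene called at 10 min, 3.52 higher in the mutant (SE 0.41, limma adjusted p = 0.0041), and 106 genes had an unadjusted p under 0.05; r between the slides was 0.22. Leaving out 1 extract gave 0 or 1 calls at 10 min, and 12 extract levels gave 0, with 14 at an unadjusted p under 0.05.

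At 30 min 5 genes were higher and 9 lower in the mutant. Only 1 array pairs the 2 strains at this time, with replicate 1 of both on slide 003. The other links between them at 30 min run through arrays that pair unlike times. lp_2335 was higher by 3.50 (SE 0.41, limma adjusted p = 0.0018) and lp_2334 by 3.41 (SE 0.51, limma adjusted p = 0.0059; 4.13 and 1.64 in the 2 replicates), each being above background on 3 of the 6 wild-type arrays. lp_1836 was lower, at -2.17 (SE 0.36, limma adjusted p = 0.0070; -2.78 and -1.52), and so was lp_1556, at -1.87 (SE 0.24, limma adjusted p = 0.0020; -2.22 and -1.19). Both are genes that rose in the wild type, lp_1836 by 30 min and lp_1556 between 10 and 30 min. The wild-type 30 min extracts enter both comparisons, so these observations are not independent. Neither gene is among the 4 with a limma adjusted p under 0.05 for the difference in the 30 min response. Without the 4 weakest arrays 203 genes were called, including all 14. The fit on 12 extract levels called 0, with 96 at an unadjusted p under 0.05, and leaving out 1 extract gave 0 to 19. Slide 003 alone gave 202 calls and slide 004 alone gave 0 by limma (683 at an unadjusted p under 0.05); across 1799 genes the differences on the 2 slides correlated with r = 0.70.

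**Figure D4:**
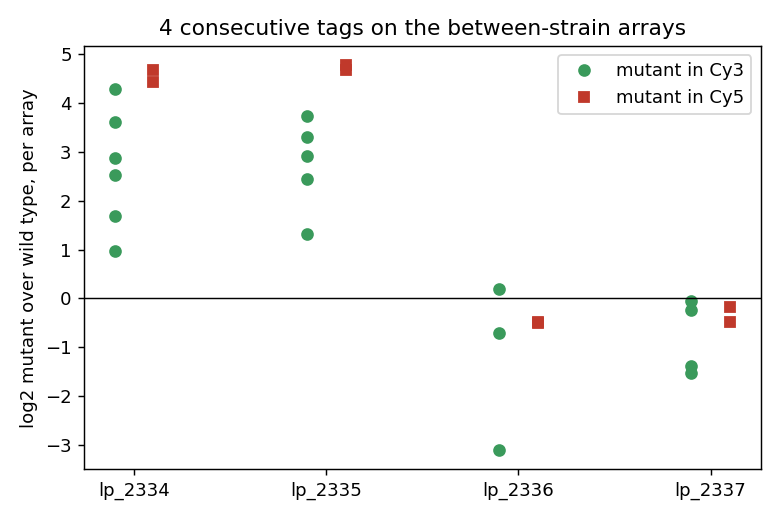
Log2 ratio of mutant over wild type on each of the 8 between-strain arrays for 4 consecutive tags, with circles where the mutant was labelled with Cy3 and squares where it was labelled with Cy5. All measured points of lp_2334 and lp_2335 lie above 0, from 0.97 to 4.78.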

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

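The strain difference in response was a comparison of the fixed design. Its use, and that of precision, as an explanation of the larger mutant response was chosen after the result was seen. So was the fit without the weak arrays, which was added once the shares of spots above background were known. At an adjusted p below 0.05, 4 genes differed in their 30 min response between the strains, although 0 passed 0.01 by limma and 464 had an unadjusted p under 0.05. The mutant's change was lower than the wild type's by -1.89 for lp_0788, by -1.32 for lp_2645, by -1.32 for lp_p3_37 and by -1.54 for lp_p3_38. In the mutant these genes changed by -1.81, -1.51, -1.20 and -1.37, and in the wild type by 0.09, -0.18, 0.12 and 0.17. Among features outside the comparisons, 6.7% of antisense spots lay above background in Cy3 against 0.5% of negative control spots; there were 5 such spots on each of the 15 arrays.

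At 30 min 223 genes were called in the mutant against 10 in the wild type, with a variance of log2 changes in excess of error 1.84 times as large (95% bootstrap interval 1.64 to 2.08 over genes). The order of the counts turned with background subtracted (246 in the mutant, 425 in the wild type), median centring (538 and 602), scale normalization (16 and 81) and 12 extract levels (1 and 2). It also turned by limma in 7 of the 12 fits that leave out 1 extract: wild type 30 min replicate 1 (0 and 2), mutant 0 min replicates 1 and 2 (1 and 2, 0 and 7), mutant 10 min replicates 1 and 2 (0 and 2, 0 and 8) and mutant 30 min replicates 1 and 2 (0 and 5, 8 and 12). The ratio of excess variances itself ran from 0.403 with scale normalization to 3.24 without wild type 0 min replicate 1. The total variance of the wild type's changes was 0.552 times the mutant's (0.496 to 0.615 over genes). Added noise would widen them, but the low variance is part of the pattern itself and cannot decide on precision. The 3 weak arrays with wild-type 30 min RNA in Cy5 had narrow gene ratios (SD 0.275, 0.295 and 0.299). The median SE was 0.174 in the wild type and 0.223 in the mutant, and for complete genes the arrays alone set its ratio. The ratio of excess variances was 1.13 without the weak array that pairs 0 and 30 min and 2.12 without the other 3 weak arrays. Without all 4 weak arrays it was 1.01 (0.919 to 1.10). That fit sets 1 replicate 1 array per strain from 0 min against the other, which the interval over genes does not cover. Removing the other 3 weak arrays did not lower the ratio. Whether the weak signal of the array that pairs 0 and 30 min, the slide or the missing second extract may be the cause cannot be told apart. A larger response of the mutant stays open, with 4 genes at an adjusted p under 0.05 for the difference and 0 called.

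The difference between the strains was larger at 30 min than at 0 min, by 4.31 times in excess variance (2.97 to 7.03 over genes). The ratio was 1.08 with 16 arrays, 1.32 without mutant 30 min replicate 1, 1.50 without wild type 0 min replicate 1, 1.63 without mutant 0 min replicate 1 and 1.98 without wild type 10 min replicate 1. In the other direction it was 15.6 without wild type 0 min replicate 2 and 9.17 without mutant 0 min replicate 2. Slide 004 alone gave 1.91 and slide 003 alone 7.56. The strains meet directly at 30 min on only 1 array, of replicate 1 on slide 003, while arrays of both replicates pair them at 0 min. The rest of the 30 min difference runs through arrays that pair unlike times. Without mutant 0 min replicate 1 the counts turned, with 16 called at 0 min and 5 at 30 min, and without mutant 30 min replicate 1 limma called 0 at both times, with 125 and 117 at an unadjusted p under 0.05. The fit on 12 extract levels left an excess of 0.00802 at 30 min and -0.0404 at 0 min. In the fit that gave 4.31 these were 0.121 and 0.0281. The error of the fit on extract levels holds differences between extracts and the error of the arrays that link them. Both replicate 2 levels at 0 min reach the later times only through the weak array, whose error they share. What lowers the excess cannot be told apart. With a negative excess at 0 min the fit on extract levels gives no usable ratio, so the pattern is not secured against the spread between extracts. Leaving out the weak arrays did not lower the ratio, which was then 6.38 (4.31 to 10.9 over genes). That interval does not cover the spread between extracts either. The pattern also depends on single extracts and on the array left out. A change of the strain difference with peroxide stays open as a biological explanation: tested gene by gene, it is the difference in the 30 min response given above, with 0 called by limma and 464 at an unadjusted p under 0.05.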

How the results depend on the processing

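The number of called genes depended strongly on the processing. The cause of the shifts was not tested. Whether signal over background limits the counts cannot be told apart from the slide: leaving out the dimmest 25% of probes moved few of them, mainly the mutant at 10 min, from 0 to 9, but leaving out the 4 weak arrays moved the first 4 from 7, 10, 0 and 223 to 542, 503, 563 and 682. For those 4 counts the 1 weak array that pairs 0 and 30 min was enough; without it nothing repeats the step from 0 min in a second extract. Spot flags left 639 of 3092 genes with too few arrays to test. Counts follow in 1 order: wild type at 10 and 30 min, mutant at 10 and 30 min, 30 against 10 min in the wild type and in the mutant, mutant against wild type at 0, 10 and 30 min, difference in the 10 and 30 min response, and strain difference over the 3 times. With 15 arrays they were 7, 10, 0, 223, 8, 1, 0, 1, 14, 0, 0, 4. With no background subtracted they were 0, 0, 0, 102, 0, 0, 0, 0, 0, 0, 0, 0. With background subtracted they were 202, 425, 108, 246, 6, 0, 2, 2, 97, 0, 0, 30. Median centring gave 326, 602, 374, 538, 0, 0, 3, 2, 6, 0, 0, 2. Scale normalization between arrays gave 25, 81, 1, 16, 0, 0, 0, 1, 5, 0, 0, 6. Leaving out the dimmest 25% of probes gave 8, 12, 9, 227, 8, 1, 0, 1, 15, 0, 0, 4. The median over probes gave 4, 11, 0, 190, 1, 1, 0, 1, 4, 0, 0, 4. The deposited table, with 16 arrays, gave 129, 239, 90, 507, 6, 0, 2, 2, 69, 0, 0, 16. A fit on 12 extract levels gave 0, 2, 0, 1, 0, 0, 0, 0, 0, 0, 0, 0. A dye term per slide gave 2, 11, 0, 114, 20, 0, 0, 2, 18, 0, 0, 3. Slide 003 alone, with 7 arrays, gave 550, 424, 496, 627, 0, 0, 1, 2, 202, 0, 1, 4. Slide 004 alone, with 8 arrays, gave 0, 0, 1, 1, 0, 0, 1, 0, 0, 1, 1, 1. No dye term gave 5, 14, 0, 204, 5, 1, 3, 0, 10, 0, 0, 3. An adjusted p below 0.05 with no fold minimum gave 497, 220, 581, 786, 41, 1, 6, 2, 177, 0, 4, 6. On 15 arrays the fit without the extract effect moved nothing, because its variance ratio was estimated at 0. The ratio was 12 on slide 004 alone, 0.1 with background subtracted, in the deposited table and without mutant 0 min replicate 1, 0.05 with 16 arrays, scale normalization, no dye term and without mutant 0 min replicate 2, and 0.2 in the deposited table with median centring and without mutant 10 min replicate 1. Slide 003 alone had 1 residual degree of freedom and its ratio was set to 0. Of the called genes at 10 min, 42.9% rose in the wild type with 15 arrays and 23.6% under median centring; at 30 min 60.0% rose in the wild type, 42.7% under median centring. Of the genes called in the mutant at 30 min 46.2% rose with 15 arrays and 31.2% with scale normalization. Between the strains at 30 min 35.7% were higher in the mutant with 15 arrays, 6 of 6 under median centring, 0 of 5 with scale normalization and 51.7% in the deposited table with median centring, which moved the median of all genes there by -0.16. For the mean of the 3 times 2 of 4 were higher with 15 arrays, 2 of 2 under median centring and 2 of 6 with scale normalization, and at 10 min scale normalization called 1 gene, which was lower in the mutant and not the gene called with 15 arrays. The fit with a replicate block gave 1, 9, 0, 115, 2, 0, 1, 1, 9, 0, 0, 3. The labels give the samples only a number, which overlaps with the slide (6 of the 7 slide 003 arrays hold replicate 1 alone, and all 8 of slide 004 hold replicate 2). With 2 numbers, replicate differences of the conditions correlated at a median of 0.06 (-0.47 to 0.88) over 15 pairs of conditions. 

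The fixed design had 16 arrays; leaving 1 out was chosen after the counts with 16 were seen, and its entry from deposited ratios once the files had been opened. The fit with 16 arrays gave 18, 16, 411, 1050, 0, 1, 6, 1, 13, 2, 8, 7, and without the extract effect 34, 24, 478, 1074, 13, 1, 8, 1, 20, 2, 8, 7. Chosen after seeing the data were 7 alternatives. Without the weak array that pairs 0 and 30 min the counts were 568, 521, 560, 695, 17, 1, 0, 1, 23, 0, 0, 3, and without the other 3 weak arrays 2, 2, 37, 110, 14, 0, 2, 2, 94, 0, 2, 24. Slide 004 alone without the extract effect gave 0, 0, 1, 1, 0, 0, 1, 0, 0, 1, 1, 1. Ignoring spot flags gave 0, 9, 49, 285, 0, 1, 3, 0, 12, 0, 1, 2. The deposited table with median centring gave 174, 379, 177, 574, 0, 0, 2, 2, 211, 0, 0, 12. Without the 4 weakest arrays the counts were 542, 503, 563, 682, 70, 0, 2, 6, 203, 0, 5, 53. Genes measured on all 15 arrays gave 8, 16, 15, 201, 16, 0, 0, 0, 20, 0, 0, 3. 

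Leaving out 1 extract at a time, where the lone extract left is assumed to vary like the others, gave ranges in the same order of 0 to 497, 2 to 471, 0 to 505, 0 to 632, 0 to 31, 0 to 1, 0 to 16, 0 to 1, 0 to 19, 0 to 4, 0 to 4, 0 to 5. Without wild type 0 min replicate 1 they were 0, 4, 0, 5, 12, 0, 5, 0, 19, 2, 3, 5. Without wild type 0 min replicate 2 they were 480, 471, 505, 632, 5, 1, 0, 1, 15, 1, 0, 4. Without wild type 10 min replicate 1 they were 0, 17, 0, 68, 31, 0, 0, 0, 17, 0, 0, 5. Without wild type 10 min replicate 2 they were 6, 11, 3, 33, 0, 0, 0, 0, 0, 0, 0, 0. Without wild type 30 min replicate 1 they were 0, 2, 0, 0, 0, 0, 0, 0, 0, 0, 0, 0. Without wild type 30 min replicate 2 they were 497, 350, 486, 606, 3, 0, 0, 1, 6, 0, 0, 2. Without gshF mutant 0 min replicate 1 they were 0, 2, 1, 1, 0, 0, 16, 0, 5, 4, 4, 3. Without gshF mutant 0 min replicate 2 they were 0, 7, 0, 0, 0, 1, 0, 1, 4, 0, 0, 4. Without gshF mutant 10 min replicate 1 they were 0, 2, 0, 0, 0, 0, 0, 0, 0, 0, 0, 2. Without gshF mutant 10 min replicate 2 they were 0, 8, 0, 0, 0, 0, 0, 0, 1, 0, 0, 0. Without gshF mutant 30 min replicate 1 they were 2, 5, 0, 0, 0, 0, 0, 0, 0, 0, 0, 0. Without gshF mutant 30 min replicate 2 they were 0, 12, 0, 8, 0, 0, 0, 0, 13, 0, 0, 5. Over all alternatives the named genes gave 1125 values, of which 687 kept direction and side of the threshold, 407 kept direction but lost the call, 28 gained one and 3 changed sign. The last were lp_1269 in the wild type, 30 against 10 min, at -0.34 under median centring, and lp_0928 in the mean strain difference, at 0.25 under median centring and 0.10 in the deposited table with median centring. The fixed gene lists gave no value under any setting.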

Other observations

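The tests of dye, probe, slide and local clustering were chosen after the result was seen, and the lp_p3 and tRNA classes after the IDs were seen. The lp_p3 tags, a class given by the IDs themselves, had 38 tested members. Their median log2 change in the wild type was 0.35 at 10 min and 0.42 at 30 min, with 0 members called. In the mutant it was 0.08 and 0.12, with 0 and 2 members called as lower. By camera with a preset correlation the class stood above other genes in the wild type at 30 min (adjusted p = 5.7e-05) and differed between strains in its 30 min response (adjusted p = 2.2e-05); on the 25 members measured on all arrays the preset correlation gave adjusted p = 2.5e-05 and adjusted p = 0.037, and an estimated correlation adjusted p = 0.654 and adjusted p = 0.765. The 7 tested tRNA tags had medians between -0.29 and 0.22 over the comparisons, and 0 were called.

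Genes called in the mutant at 30 min lay next to each other by tag number. Of 221 called genes with a chromosomal number, 25.3% had a neighbouring tested tag called in the same direction, against a mean of 8.9% over 10000 shuffles (permutation p = 1e-04, the smallest they can give). The longest run was lp_2448 to lp_2451, whose 4 genes changed by -1.98, -2.19, -2.12 and -2.22 in the mutant at 30 min and by -1.18, -1.23, -1.26 and -1.14 in the wild type. Replicate 2 is no separate check in each strain, since both strains' changes from 0 min there run through the same weak array. These falls rest on replicate 1. In the mutant they were -2.46, -2.63, -2.54 and -2.53 there against 0.34, -0.43, -0.29 and -0.75 in replicate 2, and in the wild type -1.70, -2.14, -2.04 and -1.91 against -0.04, -0.01, -0.04 and -0.11. lp_2451 was not above background on any of the 5 mutant arrays at 30 min. Its log2 changes in the mutant given above are therefore estimates from signal at background. Its mean log2 levels over both replicates, 8.87 at 0 min and 6.96 at 30 min, give a 3.75-fold fall, which rests on the same signal at background. That value is not a secure lower bound, since the change in replicate 2 was only -0.75 on the log2 scale. A candidate explanation is that genes of one transcription unit changed together, whether with peroxide or only between the 0 min extracts; operon maps were not used here.

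The excess of lp_2334 and lp_2335 in the mutant was weighed against technical explanations. Dye bias is argued against: the lowest ratio over both genes was 0.97 with the mutant in Cy3 and 4.43 with it in Cy5. These 2 values are not like for like, since the 0.97 comes from an array that pairs mutant 10 min with wild type 30 min. On the arrays that pair 0 min in both strains, with the mutant in Cy3, the ratios were 4.29 and 2.52 for lp_2334 and 3.73 for lp_2335. A single faulty probe is argued against, as the lowest mean over the 6 probes of both genes was 2.80. A slide effect is argued against, as the lowest within-slide difference was 3.34, with lp_2335 tested on slide 004 alone. The next tags did not share it. lp_2337 differed by -1.27 at 0 min (limma adjusted p = 0.011), -0.20 at 10 min (limma adjusted p = 0.99) and -0.42 at 30 min (limma adjusted p = 0.12). lp_2336, not tested, had ratios of -3.11, -0.50, -0.71, 0.19 and -0.48 on the 5 between-strain arrays that measured it. Of these, -0.71 and 0.19 come from arrays that pair unlike times. Of 6 genes with an adjusted p under 0.05 for the mean of the 3 times, 3 lay within 4 consecutive tags (permutation p = 1e-04, the smallest that 10000 draws can give). Direction did not enter this count: lp_2334 and lp_2335 were higher in the mutant, but lp_2337 was lower, at -0.63 (limma adjusted p = 0.033). That window was set after the neighbouring tags had been seen, so the p restates them and supports no cause. A local effect of the insertion stays open and needs the tag of gshF.

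For the mean of the 3 times, strain labels were exchanged within each time in 100 of the 108 distinct splits, the real one included. In 15 of them at least as many genes were called as the real 4, and the highest other split called 53, so chance cannot be excluded for this count. Some splits call many times the real number, which points to a structure of the samples. All 14 other splits with as many calls separate the replicate numbers at 1 or more times, and 1 of the 4 that separate them at all 3 times called 5. Of the 29 splits that separate them at no time, only the real one called any gene, a count looked at after the result. The high counts lie among splits that separate the replicate numbers, but only 20 of these 71 splits called any gene. The fit with a replicate block still called 3 genes for this mean. The replicate numbers overlap with the slides: 6 of the 7 slide 003 arrays hold replicate 1 alone, and all 8 of slide 004 hold replicate 2. Whether either is the source of the high counts was not tested. Within slides the difference of lp_2334 was 4.46 on slide 003 and 3.34 on slide 004.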
